A study of Mus musculus with 8 samples.

How the data were processed

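Ribosome profiling (Ribo-seq, sequencing of the mRNA fragments that ribosomes protect from nuclease) and RNA-seq were carried out on cardiac fibroblasts from wild-type mice aged 1 to 3 days, per the labels. Day 0 was the primary culture and day 5 was the culture infected with a retrovirus that encodes Mef2c, Gata4 and Tbx5 in one transcript (MGT). Per the labels' protocols, cells of each sample were washed and lysed in the presence of cycloheximide, which holds ribosomes on mRNA, and every biological replicate gave both libraries from a single lysate, 10% of it for RNA-seq and 90% for nuclease digestion and Ribo-seq. No uninfected or empty-vector culture at day 5 was analysed here, so that time in culture, infection and the factors differed together between the days. How many animals or separate cultures stood behind a replicate was not given in the sources used here.

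The deposited values were raw counts per Ensembl gene, whole numbers in 1 table per assay with 1 column per library, as the authors deposited them. Bowtie2, FastQC and the mouse genome build mm10 are named in the submitters' processing notes, with no role or version. The counting tool, its annotation, the region counted (coding sequence or whole transcript), the strand setting and any filter were not given in the sources used here. Reads of overlapping or antisense genes could therefore not be told apart, and genes with near-identical copies (ribosomal proteins, histones, globins) are uncertain where the counting could split their reads. The tables held 22430 genes, of which 22376 matched GENCODE M21 (GRCm38) by identifier and 21759 of these were protein coding. The other 54 held 0.0557% of all counts and were kept under their identifiers. Symbols shared by a second identifier (26 identifiers) were kept apart. Gene positions, the 3' UTR and coding sequence (CDS) lengths and GC content were taken from that annotation and its transcripts.

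Total counts were 11354153 and 10085644 in the day 0 RNA libraries, 6392003 and 7324215 in the day 5 RNA libraries, 2113225 and 1148576 in the day 0 Ribo-seq libraries, and 6141653 and 3996467 in the day 5 Ribo-seq libraries. Replicates differed by more than sampling noise in every group (chi-square per degree of freedom 56.0, 10.5, 2.57 and 2.76 in the same order of groups), so none was treated as a repeat of another. Counting intervals cover counting error only (95% confidence, exact conditional binomial). The floor for a group at 0 was 3 counts over the group. In such genes the fitted fold change depends on the prior count, so the bound at the floor is given, and with 1 to 3 counts in a group the ratio with its interval.

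Samples were grouped by the day and assay in their labels, into 4 groups of 2. RNA abundance and footprints were each tested within 4 libraries, day 5 against day 0, with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test with robust dispersions, TMM normalization, filterByExpr with a minimum count of 10 and a minimum total of 15, Benjamini-Hochberg adjustment, threshold 0.05). Translational efficiency, the footprint level relative to the RNA level, was tested as the interaction of day and assay in one edgeR model over all 8 libraries, with TMM factors computed within each assay, for genes that passed the filter in both. The translational efficiency model gave each gene 1 dispersion for both assays. The biological coefficient of variation was 28.3% in the RNA fit, 9% in the footprint fit and 21.9% in this model. Its errors and p-values can therefore be too small where the RNA change dominates. With 2 replicates against 2, an exact rank test could not give a two-sided p under 0.333, so significance rests on the model. The errors of log2 fold changes are approximate standard errors, the absolute log2 fold change divided by the square root of the edgeR F statistic. They can lie below the counting error where a group held few counts. The errors of levels are SDs in CPM of TMM-scaled libraries. The relation of footprint to RNA changes was described across genes by Pearson's r, Spearman's rho and the total least squares slope, with no p-value, since genes are not replicates.

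The 31 gene lists, the tests and the rule for the genes named were fixed before the data were examined. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 on log CPM with a prior count of 2. Members past the threshold were counted over all genes tested and adjusted over the list alone. The genes named were Mef2c, Gata4, Tbx5, Ybx1, Srf and Smarcd3 in every comparison, the 5 largest rises and 5 largest falls of each comparison among genes past the threshold with groups apart and a mean of at least 10 CPM (passing over predicted genes), and up to 4 members of each list with the lowest p. Some genes that this rule selects are not reported here.

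Each step was tested on simulated counts drawn from the real means, library sizes and dispersions with 200 genes changed. In the RNA comparison (11891 genes) 17.3% of 2-fold and 71.4% of 4-fold changes were recovered, and 5.43% of calls were unchanged genes. In the footprint comparison (10761 genes) the shares were 69% and 92.9%, with 6.98% false calls, and in the translational efficiency comparison (10408 genes) 2% and 47.4%, with 4% false calls. The simulated footprint comparison thus recovered small changes far more often than the others. Only 200 genes were changed in each simulation, while 5144 of 10626 were called for translational efficiency in the real data. The adjusted threshold was therefore stricter in the simulation, and these shares do not give the power in the real data. Simulated counts were drawn gene by gene from the dispersions that the fit assumes, with no trend shared across the genes of a library. The shares of false calls therefore do not give those in the real data either. A translational efficiency result that missed the threshold does not by itself show that there was no change.

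Alternatives were other normalizations (relative log expression, upper quartile, TMM over all 8 libraries), other filters, DESeq2 1.42.0, limma-voom, removal of mitochondrially encoded genes and the 10 genes with most counts, each library left out in turn, a replicate block, a fit of all 8 libraries, an estimated correlation and fry for lists, a prior count of 5, and a threshold of 0.1 for the classes of genes. After the data were seen, a smooth trend of each library on 3' UTR length, CDS length and GC content was removed as an offset (mgcv 1.9.3). This was done for the 10448 genes with values among the 10626 tested in both assays. Genes with a 3' UTR of at least 1000 nt were also tested among themselves. On simulated counts with a planted 3' UTR trend, 1643 of 10369 genes were called before that correction and 0 of 10194 after it. These genes had no other change, so the simulation does not show whether the correction keeps real changes that go with these features. The lysate pairs an RNA library with a Ribo-seq library by the labels' protocol. Across 10626 genes the deviations of the members of such pairs from their group means correlated with r = 0.0612 at day 0 and r = -0.0127 at day 5.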

Results

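Direct cardiac reprogramming drives fibroblasts toward a cardiomyocyte-like state by forced expression of cardiac transcription factors. Ribosome footprints and RNA were measured in mouse neonatal cardiac fibroblasts as primary cells (day 0) and 5 days after infection with the MGT retrovirus (day 5), with 2 replicate lysates per day and 1 Ribo-seq and 1 RNA-seq library from each lysate. Time in culture, infection and the factors changed together between the days. The RNA libraries held 11354153 and 10085644 counts at day 0 and 6392003 and 7324215 at day 5. The Ribo-seq libraries held 2113225 and 1148576 counts at day 0 and 6141653 and 3996467 at day 5, so that low footprint levels were measured least precisely at day 0. Changes are given as log2 fold changes of day 5 against day 0 ± an approximate SE derived from the edgeR F statistic. Each has n = 2 lysates per day and a Benjamini-Hochberg adjusted p. With few counts in a group that SE can understate the error. Levels are given in CPM, counts scaled to a common library size.

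Which genes gained or lost ribosome footprints was the first comparison. Footprints of all 3 reprogramming factors rose. Tbx5, a T-box factor of heart development (ENSMUSG00000018263, chromosome 5, 119832668 to 119885219, GRCm38), went from 20.3 ± 1.23 to 1341 ± 61.2 CPM (SD, n = 2), a 66.8-fold rise (log2 6.06 ± 0.16, adjusted p = 2.42e-40). Mef2c, a MADS-box muscle factor (ENSMUSG00000005583, chromosome 13, 83504034 to 83667080), rose 20.6-fold from 45.2 ± 3.26 to 920 ± 89.2 (log2 4.36 ± 0.14, adjusted p = 7.21e-35). The zinc finger factor Gata4 (ENSMUSG00000021944, chromosome 14, 63198922 to 63271692) rose 4.60-fold from 199.8 ± 22.3 to 927 ± 120.0 (log2 2.20 ± 0.12, adjusted p = 7.38e-24). Counts of these genes do not separate the endogenous copy from the vector insert.

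Ybx1, the cold-shock RNA-binding protein named in the study's title (ENSMUSG00000028639, chromosome 4, 119277981 to 119294604), had 213.8 ± 13.8 footprint CPM at day 0 and 195 ± 10.4 at day 5, a log2 difference of -0.12 ± 0.13 that missed the threshold (adjusted p = 0.449). Srf, a factor that drives muscle and cytoskeletal genes (ENSMUSG00000015605, chromosome 17, 46548329 to 46556175), fell by 0.78 ± 0.21 on the log2 scale (adjusted p = 0.00152). Its call was lost without day 5 replicate 1 (-0.70, adjusted p = 0.0645), in a fit of all 8 libraries (adjusted p = 0.0629), and with the trend on 3' UTR length, CDS length and GC removed (-0.10, adjusted p = 0.738). The chromatin remodelling subunit Smarcd3 (ENSMUSG00000028949, chromosome 5, 24590818 to 24624411) rose by 0.38 ± 0.14 (adjusted p = 0.0236), a call lost without day 0 replicate 1 (adjusted p = 0.0691), day 5 replicate 1 (0.1195) or day 5 replicate 2 (0.201), with DESeq2 (0.122), with upper quartile scaling (0.0620) and in the fit of all 8 libraries (0.324).

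**Figure D1:**
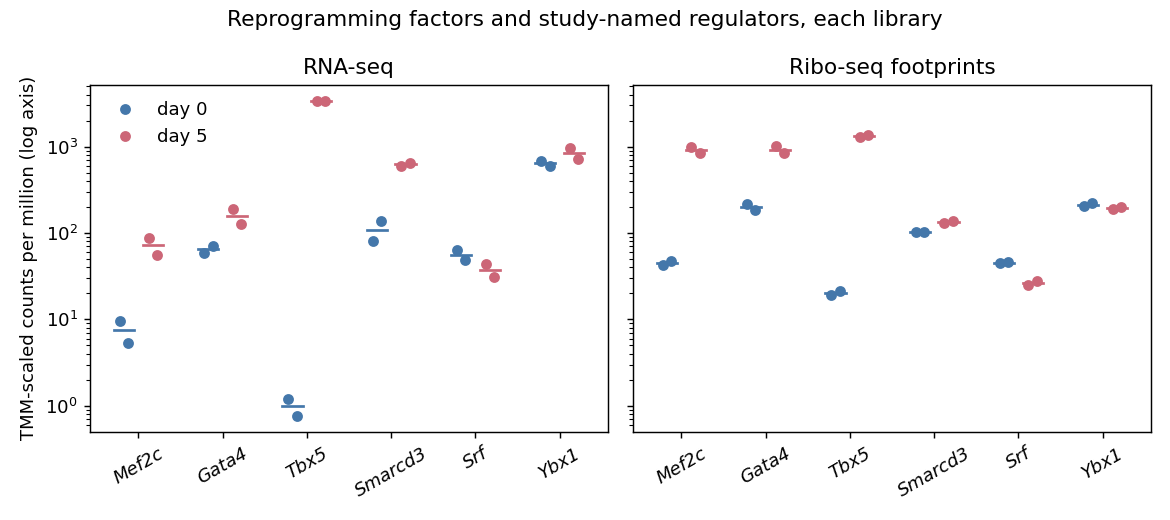
Levels of the 3 reprogramming factors and of Smarcd3, Srf and Ybx1 in every library, as TMM-scaled CPM on a log axis, for RNA-seq and Ribo-seq (points, libraries at day 0 in blue and day 5 in red, short lines, means of 2). Tbx5 RNA rose from 0.985 to 3402 CPM while its footprints rose from 20.3 to 1341, and Ybx1 stayed between 195 and 214 in mean footprint level.

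Heart muscle genes gained footprints as groups. Of 27 tested sarcomere genes, which build the contractile apparatus, 20 rose, 4 fell and 3 were not called (20 and 4 adjusted over the list alone; list adjusted p = 3.06e-06, and adjusted p = 0.240 with an estimated correlation). The atrial light chain Myl7 rose 73.7-fold (6.203 ± 0.16, adjusted p = 2.62e-36), Myl4, a light chain of atrial and embryonic muscle, 34.1-fold (5.09 ± 0.12, adjusted p = 1.54e-42), the giant spring protein gene Ttn 29.4-fold and the intermediate filament gene Des 15.1-fold. Of 19 genes of calcium handling, conduction and cardiac hormones, 16 rose, 2 fell and 1 was not called (16 and 2 adjusted over the list alone; list adjusted p = 2.67e-06, and adjusted p = 0.240 with an estimated correlation). Among them were Corin, the protease that activates natriuretic peptides (5.43 ± 0.29), the calcium store protein gene Casq2 (4.41 ± 0.16), the calcium release channel gene Ryr2 (3.71 ± 0.19) and the calcium pump gene Atp2a2 (2.83 ± 0.11). Of 12 cardiac transcription and chromatin regulators, 5 rose, 3 fell and 4 were not called (5 and 3 adjusted over the list alone; list adjusted p = 0.0945). The muscle ankyrin repeat gene Ankrd1 rose by 2.06 ± 0.11 and the smooth and cardiac muscle coactivator gene Myocd by 1.84 ± 0.23, and Hopx, a homeodomain-only protein of the developing heart, by 2.52 ± 0.42. Smyd1, a muscle methyltransferase with 2 footprint counts over both day 0 libraries, had a day 5 to day 0 ratio of 36.2 (95% counting interval 9.90 to 301).

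Fibroblast genes mostly lost footprints. Of 29 fibroblast and extracellular matrix genes 22 fell, 4 rose and 3 were not called (22 and 4 adjusted over the list alone; list adjusted p = 0.000128, and adjusted p = 0.336 with an estimated correlation). The collagen and elastin crosslinking enzyme gene Loxl1 fell by 2.23 ± 0.11, the fibrillar collagen gene Col3a1 by 1.81 ± 0.10 and the matrix glycoprotein gene Fbln2 by 1.80 ± 0.10, while Col6a3, a chain of microfibrillar collagen, rose by 1.91 ± 0.10. Of 17 genes of the TGF-beta and BMP response, 12 fell and 2 rose (13 and 3 adjusted over the list alone; list adjusted p = 0.0101, and adjusted p = 0.268 with an estimated correlation). Those that fell included the inhibitory Smad gene Smad6 (-3.71 ± 0.19) and the HLH inhibitor genes Id1 (-3.14 ± 0.21) and Id3 (-1.77 ± 0.14), all known BMP targets, while the ligand gene Tgfb2 rose (1.06 ± 0.12), a call lost in the fit of all 8 libraries (adjusted p = 0.0717). Of 13 smooth muscle and myofibroblast genes 8 fell and 2 rose (8 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.177). Lmod1, an actin nucleator of smooth muscle, fell by 1.62 ± 0.16 and Smtn by 1.26 ± 0.14.

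Markers of other heart cell types moved apart. Of 12 endothelial markers 8 fell, 1 rose and 3 were not called (8 and 1 adjusted over the list alone; list adjusted p = 0.000553, and adjusted p = 0.240 with an estimated correlation). The adhesion genes Cdh5 (-4.75 ± 0.25) and Pecam1 (-4.05 ± 0.50) and the angiopoietin receptor gene Tek (-3.47 ± 0.47) fell, while the VEGF receptor gene Kdr rose (2.34 ± 0.30). Of 15 macrophage markers 10 rose and 2 fell (10 and 2 adjusted over the list alone; list adjusted p = 0.00254, and adjusted p = 0.240 with an estimated correlation). By lowest p these were the lysozyme gene Lyz2 (10.9-fold, 3.45 ± 0.13), the integrin gene Itgam (1.49 ± 0.20), the cathepsin gene Ctss (0.88 ± 0.12) and Cd68 (1.44 ± 0.18). Of 7 pericyte markers 4 fell and 0 rose at the threshold in edgeR (4 and 0 adjusted over the list alone), among them Notch3 (-1.76 ± 0.14) and the PDGF receptor gene Pdgfrb (-1.62 ± 0.11). The pericyte list (adjusted p = 0.0387, and adjusted p = 0.299 with an estimated correlation) was not called without day 0 replicate 1 (adjusted p = 0.0947). Of 10 epicardial and mesothelial markers 5 fell and 2 rose (6 and 3 adjusted over the list alone; list adjusted p = 0.0716). Among these Lrrn4 fell 19.9-fold and the epicardial factor gene Wt1 4.82-fold, while the uroplakin gene Upk1b rose 3.53-fold, a call lost in the fit of all 8 libraries (adjusted p = 0.0620).

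Proliferation, integrated stress response and antiviral genes mostly lost footprints. Of 25 cell cycle genes 17 fell and 1 rose (19 and 1 adjusted over the list alone; list adjusted p = 2.90e-05, and adjusted p = 0.240 with an estimated correlation). Among them were the mitotic kinase gene Plk1 (-1.64 ± 0.17) and the topoisomerase gene Top2a (-1.26 ± 0.13). Of 15 replication-dependent histone genes 12 fell and 0 rose in edgeR (14 and 0 adjusted over the list alone; list adjusted p = 9.32e-05, and adjusted p = 0.299 with an estimated correlation). The linker histone genes Hist1h1d (-1.77 ± 0.14) and Hist1h1b (-1.26 ± 0.13) both fell. Of 23 genes of the integrated stress response, the programme downstream of eIF2alpha phosphorylation, 18 fell and 3 rose (19 and 3 adjusted over the list alone; list adjusted p = 1.15e-05, and adjusted p = 0.240 with an estimated correlation). Its central factor gene Atf4 fell 4.89-fold (-2.29 ± 0.13), the pseudokinase gene Trib3 6.39-fold (-2.68 ± 0.21), Atf5 4.80-fold and the serine-glycine enzyme gene Shmt2 3.80-fold. Of 19 interferon and antiviral genes 15 fell and 0 rose in edgeR (16 and 0 adjusted over the list alone; list adjusted p = 8.97e-06, and adjusted p = 0.240 with an estimated correlation). Usp18 (-1.96 ± 0.25), Isg15 (-1.23 ± 0.17) and the virus tether gene Bst2 (-1.13 ± 0.14) were lower.

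Genes of the translation and respiratory machinery also changed in footprints. Of 40 tested cytosolic ribosomal protein genes 16 fell, 4 rose and 20 were not called (17 and 4 adjusted over the list alone; list adjusted p = 0.00419, and adjusted p = 0.240 with an estimated correlation). Rps26 (-2.89 ± 0.21) and Rplp0 (-1.89 ± 0.14) fell. These genes held 0.463% and 0.470% of day 0 footprint counts and 0.378% and 0.395% of day 5 footprint counts. A median of only 2.98% of their coding 28-mers were absent from other annotated transcripts, so their footprint counts are uncertain. Of 17 other mRNAs with a 5' TOP motif, the pyrimidine start that marks translation factor mRNAs, 9 fell and 1 rose (9 and 2 adjusted over the list alone; list adjusted p = 0.0155, and adjusted p = 0.268 with an estimated correlation). Rack1 (-1.57 ± 0.11) and the elongation factor gene Eef2 (-1.22 ± 0.10) fell. Of 67 nuclear-encoded genes of oxidative phosphorylation 29 rose, 9 fell and 29 were not called (30 and 10 adjusted over the list alone; list adjusted p = 0.00419, and adjusted p = 0.299 with an estimated correlation). The ATP synthase subunit gene Atp5j rose by 1.51 ± 0.14 and the complex II gene Sdhc by 1.27 ± 0.13, while the complex I gene Ndufs8 fell by 1.99 ± 0.12.

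The largest footprint rises by the fixed rule lay outside the lists. Ppp1r3c, a glycogen-targeting phosphatase subunit, rose 209.8-fold (7.71 ± 0.29, adjusted p = 7.30e-32). It had 4 footprint counts over both day 0 libraries and a ratio of 215 (95% counting interval 84.0 to 791), wider than that SE. Footprints of Dnajc6, Gpr165 and Clstn2 were at 0 in both day 0 libraries and were at least 47.2-fold, 28.9-fold and 22.7-fold higher at day 5. Car14, a membrane carbonic anhydrase, had 1 footprint count over both day 0 libraries and a ratio of 431 (95% counting interval 77.3 to 17050). The largest falls, with Cdh5 and Lrrn4, were those of the neuropeptide precursor gene Vgf (ratio 0.0105, 95% counting interval 0.00214 to 0.0318, from 3 counts at day 5), of Dpp4, a surface peptidase (-5.15 ± 0.48), and of Tll1 (-4.49 ± 0.37). Across all 10947 genes tested, 4650 passed the threshold, 2351 higher and 2299 lower at day 5, of which 1134 and 1138 by at least 2-fold. The groups did not overlap in 69.4% of genes, against 33.3% by chance. The count was 3049 without day 5 replicate 1, 3033 without day 5 replicate 2, 2875 with DESeq2 and 2132 in the fit of all 8 libraries. The 6 study genes as a list (adjusted p = 0.0408, and adjusted p = 0.299 with an estimated correlation) were not called without day 0 replicate 1 or 2. The vector carries Mef2c, Gata4 and Tbx5, so infection alone could raise this list.

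**Figure D2:**
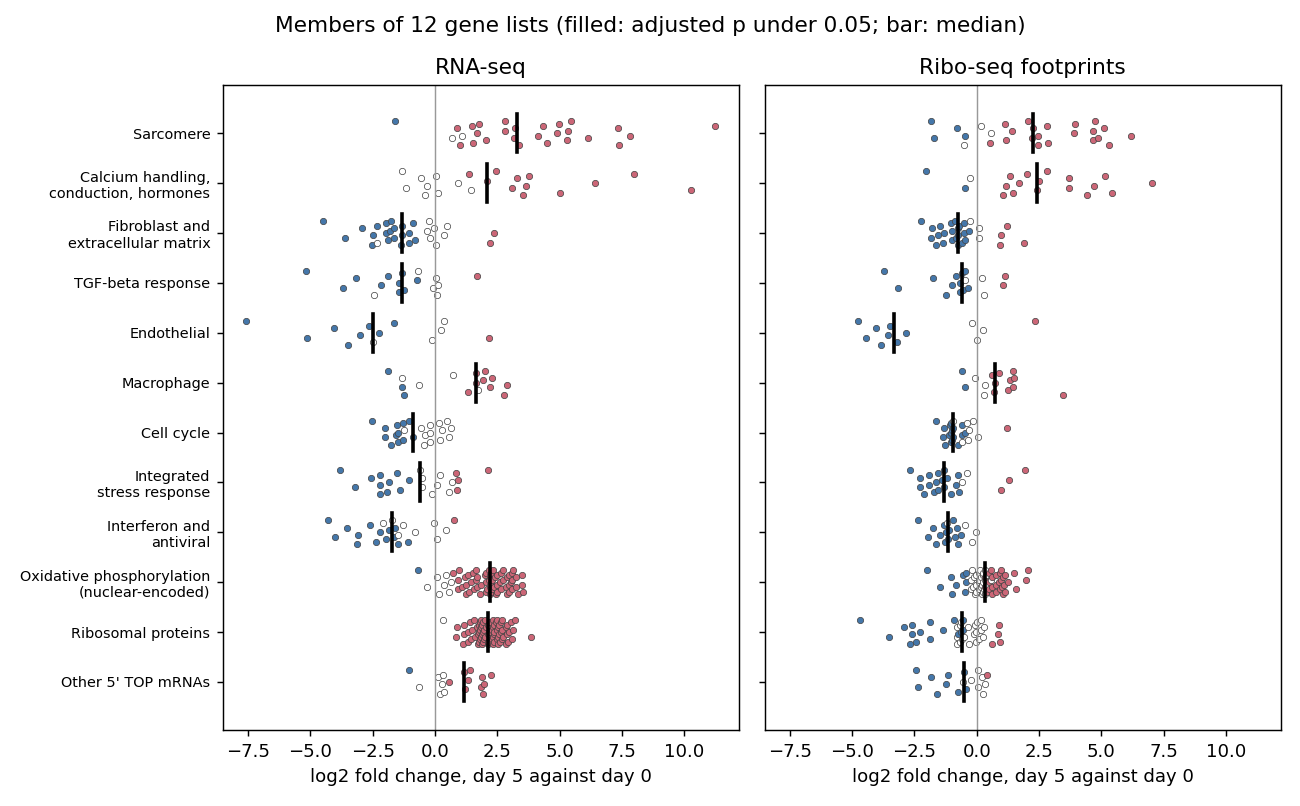
Log2 fold changes of day 5 against day 0 for the tested members of 12 gene lists in RNA-seq and Ribo-seq (points, genes, filled where the edgeR adjusted p was under 0.05; red above 0, blue below 0; bars, list medians). Sarcomere genes lie mostly above 0 in both assays, with a footprint median of 2.26, and ribosomal protein genes lie above 0 in RNA (78 of 79 called) with a footprint median of -0.60; points of genes with 3 or fewer counts in a group are fitted values.

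How RNA levels differed between the days was the second comparison. RNA of the reprogramming factors rose, Tbx5 from 0.985 ± 0.314 to 3402 ± 9.62 CPM (SD, n = 2; log2 11.72 ± 0.36, adjusted p = 4.93e-06), Mef2c 9.54-fold (3.25 ± 0.39, adjusted p = 0.000476) and Gata4 2.41-fold (1.27 ± 0.26, adjusted p = 0.00454). These rises differed widely although a single vector transcript encodes the 3 factors, so they need not give the level of that transcript. The Gata4 call was lost without day 5 replicate 1 (0.96, adjusted p = 0.0758). Smarcd3 RNA rose 5.70-fold (2.51 ± 0.29, adjusted p = 0.000428). Ybx1 RNA differed by 0.40 ± 0.23 (adjusted p = 0.161), with adjusted p = 0.0209 without day 0 replicate 1 (0.49) and a value of -0.15 with the 3' UTR, CDS and GC trend removed. Srf RNA differed by -0.60 ± 0.28 (adjusted p = 0.1015) and passed the threshold without day 0 replicate 2 (-0.77, adjusted p = 0.00914), with upper quartile scaling (-0.81, adjusted p = 0.0365) and with the trend removed (-0.98, adjusted p = 0.0333).

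RNA changes went with the length of the 3' UTR. Across 8 bins of annotated 3' UTR length the median RNA change went from 1.25 in the shortest bin to -1.31 in the bin around 2437 nt, while median footprint changes stayed between -0.07 and 0.07. Across 10448 genes, which are not independent replicates, Spearman's rho with 3' UTR length was -0.474 for RNA, 0.0639 for footprints and 0.509 for translational efficiency. The day 0 RNA libraries also differed along it (rho -0.497 for replicate 2 minus replicate 1, with bin medians spanning 1.004 log2 units), more than the day 5 RNA libraries (rho -0.122, spanning 0.176). Ribosomal protein genes took 4.46% and 5.36% of RNA counts at day 0 and 12.1% and 11.1% at day 5, and mitochondrially encoded genes 2.07% and 2.45% at day 0 and 6.90% and 6.29% at day 5.

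**Figure D3:**
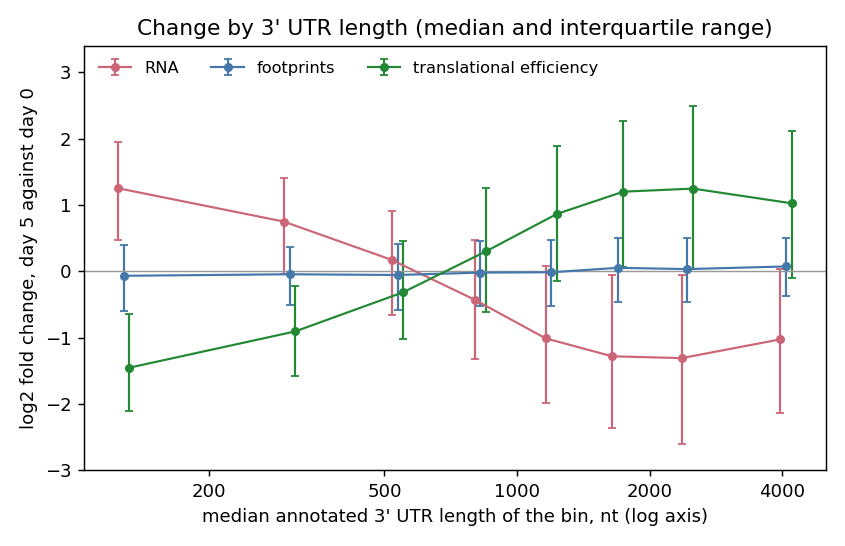
Median log2 fold change of day 5 against day 0 in 8 equal bins of annotated 3' UTR length, in nt on a log axis (points, medians of 1306 genes each; bars, interquartile range; points of the 3 measures are set slightly apart). RNA medians went from 1.25 to -1.31, translational efficiency medians from -1.45 to 1.25, and footprint medians stayed between -0.07 and 0.07.

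Sarcomere RNA rose with the footprints. Of 28 sarcomere genes (median 3' UTR 197 nt) 25 rose and 1 fell (26 and 1 adjusted over the list alone; list adjusted p = 1.61e-10, and adjusted p = 0.453 with an estimated correlation). Myl7 rose by 11.24 ± 0.85, the M-band gene Myom2 by 7.80 ± 0.44, Des by 5.45 ± 0.30 and Ttn by 5.31 ± 0.32. Their share of RNA counts went from 0.136% and 0.217% to 3.95% and 4.45%. Of the 24 members tested in both assays and with values, 20 rose with the 3' UTR, CDS and GC trend removed. Of 21 genes of calcium handling, conduction and hormones 12 rose and 0 fell in edgeR (12 and 1 adjusted over the list alone; list adjusted p = 0.00111, and adjusted p = 0.453 with an estimated correlation). Sln, an inhibitor of the calcium pump (10.28 ± 0.44), Casq2 (3.54 ± 0.26) and Popdc2 (3.07 ± 0.23) rose. Cardiac transcription regulators went both ways, with 4 of 14 rising and 4 falling (4 and 5 adjusted over the list alone; list adjusted p = 0.806). Hand2 (1.48 ± 0.24) and Hopx (3.85 ± 0.58) rose and Gata6 fell (-2.15 ± 0.34).

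Fibroblast and matrix RNA mostly fell, with 20 of 30 genes lower and 2 higher (20 and 2 adjusted over the list alone; list adjusted p = 0.00398, and adjusted p = 0.453 with an estimated correlation). Fbln2 fell by 2.52 ± 0.22, Col5a1 by 2.48 ± 0.23 and Postn by 2.33 ± 0.24, while the intermediate filament gene Vim rose by 2.36 ± 0.24. Interferon genes fell in 14 of 23 and rose in 1 (14 and 1 adjusted over the list alone; list adjusted p = 0.00204, and adjusted p = 0.616 with an estimated correlation). Stat2 (-3.54 ± 0.44) and Ifit1 (-3.09 ± 0.48) were lower. Integrated stress response genes fell in 11 of 23 and rose in 4 (13 and 5 adjusted over the list alone; list adjusted p = 0.157). With the 3' UTR, CDS and GC trend removed 12 fell and 2 rose and the list was called (adjusted p = 0.00377). The amino acid transporter gene Slc7a5 (-3.80 ± 0.43) and Trib3 (-2.19 ± 0.26) fell. Several lists passed the threshold only narrowly and not with every library left out. Cell cycle RNA (12 of 25 lower, 0 higher in edgeR; adjusted p = 0.0402, and adjusted p = 0.616 with an estimated correlation) was not called without day 0 replicate 2 (0.0579) or day 5 replicate 1 (0.155). The TGF-beta list (10 of 17 lower, 1 higher; adjusted p = 0.0464, and adjusted p = 0.453 with an estimated correlation), in which the inhibitory Smad gene Smad7 fell by 3.69 ± 0.46, was not called without day 0 replicate 2 (0.106), day 5 replicate 1 (0.0624) or day 5 replicate 2 (0.0597).

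Markers of other cell types also changed in RNA. Endothelial RNA fell for 8 of 13 markers and rose for 1 (adjusted p = 0.0402, and adjusted p = 0.453 with an estimated correlation). Cdh5 (-5.12 ± 0.63), Tek (-4.04 ± 0.73) and Pecam1 (-3.49 ± 0.57) fell and Vwf, the von Willebrand factor gene, rose (2.15 ± 0.43). The list was not called without day 0 replicate 1 (0.0658) or 2 (0.116) or with the 3' UTR, CDS and GC trend removed (0.233). Macrophage RNA rose for 9 of 16 markers and fell for 3 (adjusted p = 0.0402, and adjusted p = 0.453 with an estimated correlation). Fcer1g (2.88 ± 0.26) and Cd68 (1.92 ± 0.26) rose. That list was not called without day 5 replicate 1 (0.0579) or with the trend removed (0.209). Pericyte RNA fell for 4 of 6 markers (adjusted p = 0.04996, and adjusted p = 0.639 with an estimated correlation). Pdgfrb (-3.97 ± 0.26) and Notch3 (-2.61 ± 0.29) were lower, and the list was not called without day 0 replicate 2 (0.174) or day 5 replicate 2 (0.122) or with relative log expression scaling (0.0517). Wt1 fell by 4.56 ± 0.72 among 10 epicardial markers, of which 5 fell and 1 rose (list adjusted p = 0.488). Red cell RNA was seen at day 5. All 5 tested erythroid genes rose (list adjusted p = 0.000323, and adjusted p = 0.453 with an estimated correlation). The globin genes Hbb-bs, Hbb-bt and Hba-a1 and the anion exchanger gene Slc4a1, with no count at day 0, were at least 445-fold, 87.5-fold, 59.8-fold and 69.6-fold higher. All 8 erythroid genes had no footprint in any of the 4 Ribo-seq libraries.

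RNA of ribosomal and mitochondrial genes rose. Of 79 ribosomal protein genes (median 3' UTR 89 nt) 78 rose and 1 was not called (78 adjusted over the list alone; list adjusted p = 1.39e-21, and adjusted p = 0.453 with an estimated correlation). Rps29 rose by 3.86 ± 0.27 and Rps12 by 3.19 ± 0.23. Of the 40 members also tested in footprints, 21 rose and 3 fell with the 3' UTR, CDS and GC trend removed. Oxidative phosphorylation genes (median 3' UTR 162 nt) rose in 65 of 73 and fell in 1 (67 and 1 adjusted over the list alone; list adjusted p = 4.43e-17, and adjusted p = 0.453 with an estimated correlation). Ndufa1 rose by 3.51 ± 0.25 and Atp5e by 3.48 ± 0.25, and with the trend removed 38 of the 67 also tested in footprints rose and 4 fell. Mitochondrially encoded genes rose in 8 of 10 (8 adjusted over the list alone; list adjusted p = 0.00398, and adjusted p = 0.453 with an estimated correlation). Both mt-Nd4 (3.15 ± 0.31) and mt-Cytb (2.49 ± 0.27) rose. Other 5' TOP mRNAs rose in 10 of 17 and fell in 1 (10 and 1 adjusted over the list alone; list adjusted p = 0.00675, and adjusted p = 0.453 with an estimated correlation). Eif3k (2.25 ± 0.27) and Tpt1 (1.93 ± 0.22) rose. The 6 study genes as a list (adjusted p = 0.0315, and adjusted p = 0.453 with an estimated correlation) were not called without day 0 replicate 2. Vector RNA of Mef2c, Gata4 and Tbx5 alone could raise this list.

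By the fixed rule the largest RNA rises were those of Tbx5, Myl7, Sln, Hbb-bs and the potassium channel gene Kcnc4, the last with no count at day 0 and at least 441-fold higher at day 5. The largest falls were those of the membrane protein gene Emp1 (-5.95 ± 0.46), the amino acid transaminase gene Bcat1 (-6.01 ± 0.62), Medag (ratio 0.00691, 95% counting interval 0.000836 to 0.0251), Dpp4 (0.00825, 0.000997 to 0.0299) and the decoy receptor gene Tnfrsf11b (0.0122, 0.00252 to 0.0359), the last 3 with 2, 2 and 3 counts over both day 5 libraries. Of 12125 genes tested, 6887 passed the threshold, 3262 higher and 3625 lower, 2768 and 3340 of them by at least 2-fold. With the trend on 3' UTR length, CDS length and GC removed, 4817 of 10448 genes passed, against 6146 of the same genes before, with 3452 called in the same direction in both and 109 in opposite directions. Groups did not overlap in 84.0% of genes, against 33.3% by chance.

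Whether ribosomes per mRNA changed was the third comparison. Translational efficiency of Tbx5 fell by 5.76 ± 0.32 on the log2 scale (adjusted p = 2.36e-05) and that of Smarcd3 by 2.22 ± 0.34 (adjusted p = 0.000915), since both gained more RNA than footprints. At day 5 the ratio of Tbx5 to Mef2c counts was 38.74 and 60.65 in RNA, against 1.32 and 1.616 in footprints. A single vector transcript encodes Mef2c, Gata4 and Tbx5, so the values of these genes need not give a change in ribosomes per mRNA. For Ybx1 the change was -0.63 ± 0.27 (adjusted p = 0.0748), with adjusted p = 0.0188 without the day 0 replicate 1 lysate (-0.74). Gata4 (0.84 ± 0.32, adjusted p = 0.0505) passed with the lysate as a block (0.86, adjusted p = 0.0366), with upper quartile scaling (1.13, adjusted p = 0.0164), with no filter (1.00, adjusted p = 0.0236), with a filter at 10 CPM (0.95, adjusted p = 0.0269) and without the day 0 replicate 1 lysate (1.13, adjusted p = 0.00976). Mef2c (1.00 ± 0.42, adjusted p = 0.0695) passed with upper quartile scaling (adjusted p = 0.0284), no filter (0.0366) or without the day 0 replicate 2 lysate (0.00386), and was at -0.28 with the 3' UTR, CDS and GC trend removed. Srf was at -0.29 ± 0.36 (adjusted p = 0.529), with 0.0075 under upper quartile scaling, 0.06 without the day 5 replicate 1 lysate and 0.88 with the trend removed.

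Ribosomal protein mRNAs lost translational efficiency as a group. All 40 tested members fell (40 adjusted over the list alone; list adjusted p = 1.21e-17, and adjusted p = 0.254 with an estimated correlation), and 24 of 40 fell and 0 rose in edgeR with the 3' UTR, CDS and GC trend removed. Among them were Rps26 (-5.69 ± 0.34), Rpl14 (-5.62 ± 0.39) and Rplp1 (-4.38 ± 0.35). Only 17.45%, 13.56% and 19.81% of their coding 28-mers were absent from other annotated transcripts, so the size of these falls is uncertain. Rpl36, with a day 5 to day 0 footprint ratio of 0.0330 (95% counting interval 0.00374 to 0.136) from 2 counts at day 5, had RNA higher by 3.09 ± 0.23 on the log2 scale. Of 17 other 5' TOP mRNAs 14 fell and 0 rose in edgeR (14 and 0 adjusted over the list alone; list adjusted p = 3.52e-06, and adjusted p = 0.240 with an estimated correlation). Tpt1 was at -3.88 ± 0.35, Rack1 at -3.004 ± 0.26 and Eef2 at -1.69 ± 0.21, and 12 of 17 fell with the trend removed. The share of coding 28-mers absent from other transcripts was 0% in Rpl36 and in Tpt1, 94.5% in Rack1 and 68.35% in Eef2. Of 67 oxidative phosphorylation genes 55 fell and 2 rose (56 and 2 adjusted over the list alone; list adjusted p = 2.26e-15, and adjusted p = 0.806 with an estimated correlation). Ndufs8 (-4.58 ± 0.41) and Atp5e (-3.55 ± 0.36) fell. With the trend removed 21 fell and 8 rose and the list was no longer called (adjusted p = 0.0675).

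Sarcomere mRNAs also moved down in translational efficiency, 14 of 26 falling and 3 rising (14 and 4 adjusted over the list alone; list adjusted p = 0.00129, and adjusted p = 0.893 with an estimated correlation). Myl7 (-5.08 ± 0.83) and Myh7 (-3.99 ± 0.65) fell. Removing the 3' UTR, CDS and GC trend left 9 of 24 falling and 1 rising. Calcium handling genes were not called as a list (adjusted p = 0.824), although the long 3' UTR mRNAs Atp2a2 (3.27 ± 0.33) and the gap junction gene Gja1 (3.07 ± 0.42) rose. Fibroblast and matrix genes rose in 14 of 29 and fell in 6 (14 and 6 adjusted over the list alone; list adjusted p = 0.602), with Bgn at 1.96 ± 0.26 and Loxl1 at -2.08 ± 0.29. In the integrated stress response list 10 of 23 fell and 6 rose (11 and 6 adjusted over the list alone; list adjusted p = 0.420). Its members Ppp1r15a (-3.79 ± 0.39), Atf4 (-3.30 ± 0.31) and Atf5 (-3.05 ± 0.38) fell, and were at -2.67, -1.95 and -1.70 with the 3' UTR, CDS and GC trend removed.

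The largest rises by the fixed rule were in genes with almost no RNA counts at day 5. Peg10 had an RNA ratio of 0.00633 (95% counting interval 0.000160 to 0.0355) and Zfp518b one of 0.0126 (0.000319 to 0.0711), each with 1 RNA count over both day 5 libraries. Robo1, Kcnj15 and Plagl1 had none, so that their translational efficiency was at least 11.6-fold, 6.41-fold and 6.34-fold higher at the floor of 3 counts over the group. The edgeR calls of Kcnj15 without day 5 replicate 2 (adjusted p = 0.0629) and of Plagl1 without day 5 replicate 1 (0.131) or 2 (0.117) were lost, and that of Plagl1 also with the 3' UTR, CDS and GC trend removed (0.1017). Besides Tbx5, Rps26, Rpl14 and Rpl36, the largest falls included the histone gene Hist1h4h (-5.96 ± 0.65). Of 10626 genes tested, 5144 passed, 2832 higher and 2312 lower, in a model that gave both assays 1 dispersion per gene. With upper quartile scaling 3498 were higher and 1741 lower. Groups did not overlap in 78.3% of genes, against 33.3% by chance. The count was 2175 without the day 5 replicate 1 lysate and 1643 without that of replicate 2. With the 3' UTR, CDS and GC trend removed it was 3381 of 10448 genes, against 5060 of the same genes before, with 2409 in the same direction in both and 37 in opposite directions.

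How far footprints followed RNA was described across the 10626 genes tested in both assays, which are not independent replicates. Fold changes correlated with Pearson's r = 0.394 and Spearman's rho = 0.228, and the total least squares slope of footprint on RNA changes was 0.315 (SD 0.124 over the 4 pairings of replicates). That slope was 0.571 without the day 0 replicate 1 lysate and 0.504 with the 3' UTR, CDS and GC trend removed. Myl7, Des and Ttn were among the 870 genes higher in both assays, where independent lists would share 582, and Fbln2, Cdh5 and Pdgfrb among the 1029 lower in both, where independent lists would share 736. A further 395 genes were higher in RNA and lower in footprints, and 572 lower in RNA and higher in footprints, fewer than the 580 and 739 that independent lists would share. Of the 5144 genes with a translational efficiency call, 2581 (50.2%) changed in RNA in the opposite direction with no footprint call. Calls against the RNA change came with footprints moving opposite to the RNA in 967 genes and with it in 671, and 716 genes, the cell cycle inhibitor gene Cdkn1a among them, had footprint and translational efficiency calls without an RNA call. RNA and footprints changed the same way with no translational efficiency call in 1181 genes. Since translational efficiency contains the RNA change with a negative sign, its Spearman correlation with it (-0.846) is partly set by construction.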

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

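Of the genes named in the comparisons, 62 of 67 in RNA, 81 of 90 in footprints and 38 of 47 in translational efficiency kept their direction and their side of the threshold under every alternative that held the gene. The restriction to long 3' UTRs held only 31, 39 and 22 of them. Apart from the study genes, the named genes were chosen from the same data for large changes or low p-values. The shares kept therefore do not give the stability of calls over all genes tested. Among 10448 genes, 2409 of 5060 translational efficiency calls were kept in the same direction with the 3' UTR, CDS and GC trend removed. With the trend on 3' UTR length, CDS length and GC removed, Ybx1 RNA turned to -0.1477, Mef2c translational efficiency to -0.2839 and Srf translational efficiency to 0.8808. Srf translational efficiency was also 0.0075 with upper quartile scaling and ranged from -0.6043 to 0.0585 with each lysate left out. None of the values that turned had been called in the fit reported above, and the cause was not tested.

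Footprint calls numbered 4650 and became 2875 with DESeq2 and 2132 in the fit of all 8 libraries, which shares 1 dispersion per gene with the noisier RNA libraries. With each library left out they ranged from 3033 to 4618, RNA calls from 4648 to 8351, translational efficiency calls from 1643 to 6782, and the slope of footprint on RNA changes from 0.253254 to 0.571425. These fits hold fewer samples, and a group left with 1 library was assumed to vary like the other. With the 3' UTR, CDS and GC trend removed there were 3381 translational efficiency calls and the slope was 0.503515 (Pearson's r = 0.514, Spearman's rho = 0.343). Among genes with a 3' UTR of at least 1000 nt there were 2657 calls in RNA, 2342 in footprints and 2004 in translational efficiency, against 3294, 2336 and 2639 for the same genes in the full fit. Of the calls in the full fit, 2043, 2225 and 1550 were kept in the same direction. Normalized among themselves, these genes moved by a median of 0.868 in RNA, -0.057 in footprints and -0.871 in translational efficiency. The RNA and translational efficiency changes of single genes thus depended on which genes set the scaling. Upper quartile scaling moved the median change by -0.219 in RNA and 0.298 in translational efficiency.

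Same-numbered libraries of different days shared only a number (r = 0.118 for RNA, -0.0243 for footprints). With the replicate block there were 7437 RNA calls and 4417 footprint calls, and with the lysate as the block 5053 translational efficiency calls, of which Gata4 was the only named gene whose call changed. The class of 2581 genes held 2537 with the replicate block and 2828 at adjusted p under 0.1. In RNA the block gave adjusted p = 0.0479 for Srf, 0.0553 for the TGF-beta and macrophage lists, 0.0669 for the cell cycle list and 0.0724 for the pericyte list.

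All 35 list results past the threshold (16 in RNA, 15 in footprints, 4 in translational efficiency) were lost with an estimated correlation. With fry 14 of 16, 15 of 15 and 3 of 4 stayed. The lists lost with fry were the interferon (adjusted p = 0.0716) and pericyte (0.0525) lists in RNA and the sarcomere list in translational efficiency (0.0561). Fry, which does not set a list against other genes, also called 3 lists in RNA, 4 in footprints and 4 in translational efficiency that camera did not, the integrated stress response list in translational efficiency with the lowest adjusted p (0.000364). Depth limited low footprint levels at day 0, where 3 counts stood for 1.42 and 2.61 CPM.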

Other observations

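Several further lists of metabolism and stress genes were not called, with single members past the threshold. Of 17 fatty acid oxidation genes 6 rose and 0 fell in edgeR in footprints (list adjusted p = 0.0697), with the thiolase gene Acaa2 9.80-fold higher (log2 3.29 ± 0.15, n = 2 per day) and the electron transfer gene Etfa at 1.10 ± 0.20. In RNA Acaa2 rose by 4.23 ± 0.28 and Cpt1a, the gate of mitochondrial fatty acid entry, fell by 3.55 ± 0.49 (6 of 19 rose and 6 fell, list adjusted p = 0.599). Of 14 p53 response genes 7 rose and 4 fell in footprints (list adjusted p = 0.553), among them Ccng1 (1.48 ± 0.17), the cell cycle inhibitor gene Cdkn1a (0.99 ± 0.12) and, falling, Bax (-0.65 ± 0.12). Footprints of glycolysis genes went both ways (4 of 13 rose, 3 fell, adjusted p = 0.700), with the lactate exporter gene Slc16a3 at -2.42 ± 0.19, as did autophagy genes (4 of 16 rose, 3 fell, adjusted p = 0.360; Ctsb 0.89 ± 0.10, Sqstm1 -0.82 ± 0.11) and secretory stress genes (7 of 20 rose, 2 fell, adjusted p = 0.349; P4hb 0.59 ± 0.10, Serpinh1 -0.79 ± 0.10). Of 16 cholesterol synthesis genes 1 rose and 4 fell in footprints (list adjusted p = 0.0716). The RNA lists of p53 (adjusted p = 0.503, and 0.0166 with the 3' UTR, CDS and GC trend removed, 7 of 13 lower), glycolysis (0.806), autophagy (0.503), secretory stress (0.806) and smooth muscle (0.966) were not called. In RNA 8 of 16 cholesterol synthesis genes fell and 2 rose (list adjusted p = 0.0882, median -0.971), and with the trend removed 5 fell and 0 rose in edgeR (adjusted p = 0.25, median -0.142).

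Among 6 tested inflammatory genes 3 rose and 3 fell in footprints (list adjusted p = 0.744; RNA 0.806), with Il6 at -2.16 ± 0.38 and Ccl2 at -1.53 ± 0.22. Of 30 translation initiation and RNA-binding repressor genes 9 rose and 6 fell in footprints (list adjusted p = 0.839), with the splicing regulator gene Celf2 at 1.65 ± 0.13 and the eIF4E inhibitor gene Eif4ebp1 at -1.03 ± 0.14, while in RNA 4 rose and 14 fell (list adjusted p = 0.0923), including Caprin1 (-3.24 ± 0.51). Skeletal muscle RNA rose for 6 of 7 genes (list adjusted p = 0.000698, and adjusted p = 0.453 with an estimated correlation), with Tnnt3 at 6.12 ± 0.49 and the perinatal myosin gene Myh8 at 7.11 ± 0.62, and Myh8 footprints, at 0 in both day 0 libraries, were at least 19.6-fold higher. Of the Schwann and neural list only Tubb3 was tested in footprints and fell 9.59-fold. Of lymphocyte genes none passed the filter in either assay. Of the 25 lists tested for translational efficiency 21 were not called, and the lowest adjusted p among these was 0.420, that of the integrated stress response. With the 3' UTR, CDS and GC trend removed the p53 list alone among these was called, higher (adjusted p = 0.00311, 5 of 13 rose and 1 fell).

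All tests of technical causes given below, except the thinning of counts, were chosen only after the results they concern had been seen, and so were the bounds used for the day 0 libraries and for the unique-sequence members.

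The first pattern was the course of RNA and translational efficiency changes with 3' UTR length, where the RNA rho within strata of CDS length and GC was -0.386. The log2 ratio of Tbx5 over Mef2c counts at day 5 was 5.053 higher in RNA than in footprints, and both values are consistent with day 5 RNA reads lying nearer to the 3' ends of transcripts, the first only if reads were counted on coding sequence, which the sources used here do not give, the second only if Tbx5 is the last insert, as in the construct's name. Fewer counts alone did not account for the trend, since thinned day 0 libraries kept a share of 1.004 of the rho. Thinning leaves the expected share of each gene unchanged, so it does not test other differences between libraries that go with lower depth. The footprint rho of 0.0639 argues against a change of translation alone, although it ranged from -0.115 to 0.217 across single strata. A real loss of long 3' UTR mRNAs offset by more ribosomes per mRNA could not be told apart, although the day 0 RNA libraries also differed along the trend (span 1.004). Translational efficiency changes of single genes are therefore open to this cause.

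The second pattern was the lower translational efficiency of ribosomal protein and other 5' TOP mRNAs. Their medians differed from those of genes matched on 3' UTR length, CDS length and GC by -1.075 and -1.543 (list medians -2.64 and -1.74) and lay lower than in every one of 1000 draws, so the trend is not the whole cause. Shared reads are not the whole cause either, since the 14 members with over 50% unique coding 28-mers lay -1.228 from matched genes. Whether the footprints of these members fell could not be settled (median -0.338, bootstrap SD 0.216, 7 fell and 0 rose). RNA lay beyond every draw only for the other 5' TOP list (1.017 above matched genes, ribosomal proteins 0.391) and footprints only for ribosomal proteins (-0.671, other 5' TOP -0.52). No biological explanation was tested.

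The third pattern was the fall of endothelial and rise of macrophage markers in footprints. A smaller share of fibroblasts as the only cause would raise both alike. The median difference of 4.082 (macrophage minus endothelial, against summed half-ranges of 2.405) argues against that, although the pattern was picked for this difference. A smaller share of fibroblasts together with a loss of endothelial cells was not tested. Fewer endothelial cells at day 5 would lower their markers in both assays, and 63.64% of 11 markers fell in both, which is consistent with such a loss. Picked after the values were seen, Flt1 (107.7 to 109.7 CPM in footprints) and Eng (417 to 361) did not pass the threshold, so a loss of endothelial cells does not account for every marker. Fewer endothelial and more macrophage cells in the day 5 cultures may thus contribute to these changes, and the effect of infection was not separable from time in culture.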
